A study of Mus musculus with 34 samples.

How the data were processed

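Gene expression was measured in mouse cells, of CD1 strain with an aMHC-GFP genotype per the labels, on 34 single-colour Agilent arrays of 60K format. Total RNA was extracted with TRIzol, purified on columns and labelled with Cy3, per the labels' protocols. Fibroblasts and cardiomyocytes came from pups at postnatal day 1.5, iCM from fibroblasts given a retrovirus with Mef2c, Gata4 and Tbx5 on 1 transcript, and iPSC lines from cardiac fibroblasts given Oct4, Sox2, Klf4 and cMyc, per the labels' protocols. The iCM and the iPSC-derived cells were kept in the same supplemented medium, per the labels' protocols. Each of the 17 groups has 2 arrays. The labels give no sort of the cells and do not say whether replicates were separate cultures.

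The scanner files hold fluorescence intensity for each spot, background-adjusted and detrended within the array by Agilent Feature Extraction 10.7.3.1, per the file headers. No scaling between arrays is recorded for those values. The authors also deposited a table of log2 values, with column medians between 7.49 and 7.52, for which the labels name limma without a version. Its columns correlated with log2 of the processed intensity at r = 0.982 or more. The main analysis used the processed intensity, and the authors' log2 values served as an alternative.

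Each array carries 59305 non-control spots for 55681 probes. Spots well above background numbered 28715 to 44881, the 75th percentile of intensity lay between 729 and 3778, no spot was saturated, and the median coefficient of variation of replicate spots was 2.31% to 5.91%. The LacZ D14 replicate 2 array was the dimmest, and the scanner software marked 17 arrays for evaluation, which were kept. Spots marked as outliers (119 to 321 an array, 6881 in all) were left out. Intensities were put on the log2 scale, spots of a probe averaged, and the 75th percentile of each array subtracted. A level is thereby relative to that percentile.

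Probes were paired with genes through RefSeq gene annotation (GRCm38.p6), used for names only: 26056 by accession, 3200 by symbol and 930 by an older symbol. A further 17104 probes had no name and 8391 only a name in the array files, and these were not tested. A probe was kept if well above background on both arrays of at least 1 group, and the probe with the highest mean over all arrays stood for its gene. This left 43382 probes, 25635 with a gene, and 19413 genes, of which 5116 had over 1 kept probe and 192 a missing value.

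All 34 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3, with data.table version 1.17.8) with a mean for each group, 17 residual and 1.99 prior degrees of freedom. Sharing the spread in this way assumes that all groups vary alike. Contrasts were moderated with eBayes and adjusted by Benjamini-Hochberg. A gene was called at adjusted p under 0.05 and at least 2-fold. Gene lists (29, fixed before any value was seen, 426 of 431 members with a probe) were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a comparison. Missing values took the group mean for camera only. Where a gene was not well above background on any array of its lower side, the change is given as an at-least fold. For each array of that side it takes the larger of the gene's value and the array's lowest signal well above background. The mean of these over the side is set against the mean of the higher side. Files were read and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

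Genes to name were set by a rule written before any value was seen. It takes, among called genes with an established symbol and well above background on the higher side, the 5 highest and 5 lowest changes, the 2 largest rises and falls in the sarcomere, fibroblast and cell cycle lists and in up to 6 further lists with the lowest camera p, and the delivered factors. The text names fewer.

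In simulated data with 200 changed genes among 19413, the fit called 69% of those changed by 1.5 on the log2 scale and 93% of those changed by 3 for iCM against iPSC-CM, with 3 false calls. For MGT against LacZ on day 7 it called 54% and 90%, with 9 false calls. The simulated noise gave every group the same spread, as the fit assumes. In the data the SD of the difference between replicates ran from 0.318 (LacZ D3) to 1.731 (iPSC2-CM D29), so these rates need not hold there.

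The headers place the arrays on 6 slides scanned on 3 days. Slide 1 held neoCM replicate 1, slide 2 neoCM replicate 2 and iCM, slides 3 and 4 the MGT and LacZ arrays of days 3 to 10, slide 5 neoCF, CF D0 and LacZ D14, and slide 6 the iPSC-derived cells and MGT D14. Slides 1 and 2 shared a scan day, as did 3 and 4, and 5 and 6. Slide was tried as a fixed block for iCM against neoCM. It was tried as a random block where the 2 sides of a comparison shared no slide (consensus correlation -0.109, estimated with limma). There a slide difference falls together with the groups, so the random block cannot remove it and its counts do not test for one. Further alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, the authors' values, no filter or a stricter one (4 groups), the mean of all probes of a gene, only the arrays compared, array weights, eBayes with trend and robust, the replicate number, no fold minimum, treat against 1.5-fold, and leaving out each array. The fit without both iPSC2-CM D29 arrays, CF D0 as the reference, and the mean over days 3 to 10 were added after seeing the data.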

Results

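RNA from 34 mouse heart-cell samples was measured on single-colour Agilent arrays, 2 arrays for each of 17 groups. The end-point groups were neonatal cardiac fibroblasts (neoCF), neonatal cardiomyocytes (neoCM), induced cardiomyocytes 4 weeks after Mef2c, Gata4 and Tbx5 (iCM), and cardiomyocytes from induced pluripotent stem cells of 2 lines. The first line was taken on day 13 (iPSC1-CM) and the second on days 9 and 29 (iPSC2-CM). A second set followed cardiac fibroblasts from day 0 (CF D0) through days 3, 5, 7, 10 and 14 after virus with the 3 factors (MGT) or with LacZ. Each array had between 28715 and 44881 of its 59305 probe spots well above background, and 19413 genes were tested. With 2 arrays a group, only changes large against the spread between replicates could be called, so an uncalled gene is not an unchanged one.

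The 2 arrays of a group correlated at r = 0.984 to 0.997 across genes in 16 groups, and at r = 0.895 in iPSC2-CM D29, where 8217 genes differed at least 2-fold between the replicates. The first principal component held 35.6% of the variance and placed neoCM and the iPSC-derived cells at one end (-203 to -110) and the LacZ cultures at the other (44.9 to 78.3). Across genes, iCM correlated most with MGT D14 (r = 0.953), followed by MGT D7 and D10 (r = 0.951 each). The LacZ cultures came close, with r = 0.943 on day 7, r = 0.941 on day 10 and r = 0.94 on day 14, against r = 0.906 with neoCF, r = 0.89 with neoCM, r = 0.883 with iPSC2-CM D29, r = 0.87 with iPSC1-CM and r = 0.829 with iPSC2-CM D9. The p-values below measure only the spread between these samples, as the labels do not say whether replicates came from separate cultures. Where camera, the test of a whole list, has 2 adjusted p-values, the first sets the correlation between genes at 0.01 and the second estimates it. Values after ± are limma standard errors on the log2 scale, with n = 2 arrays a group, and n = 4 where iPSC1-CM and iPSC2-CM D9 were averaged as iPSC-CM. The ± and p-values of iPSC-CM measure the spread between arrays of a group, not the difference between the 2 lines.

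**Figure D1:**
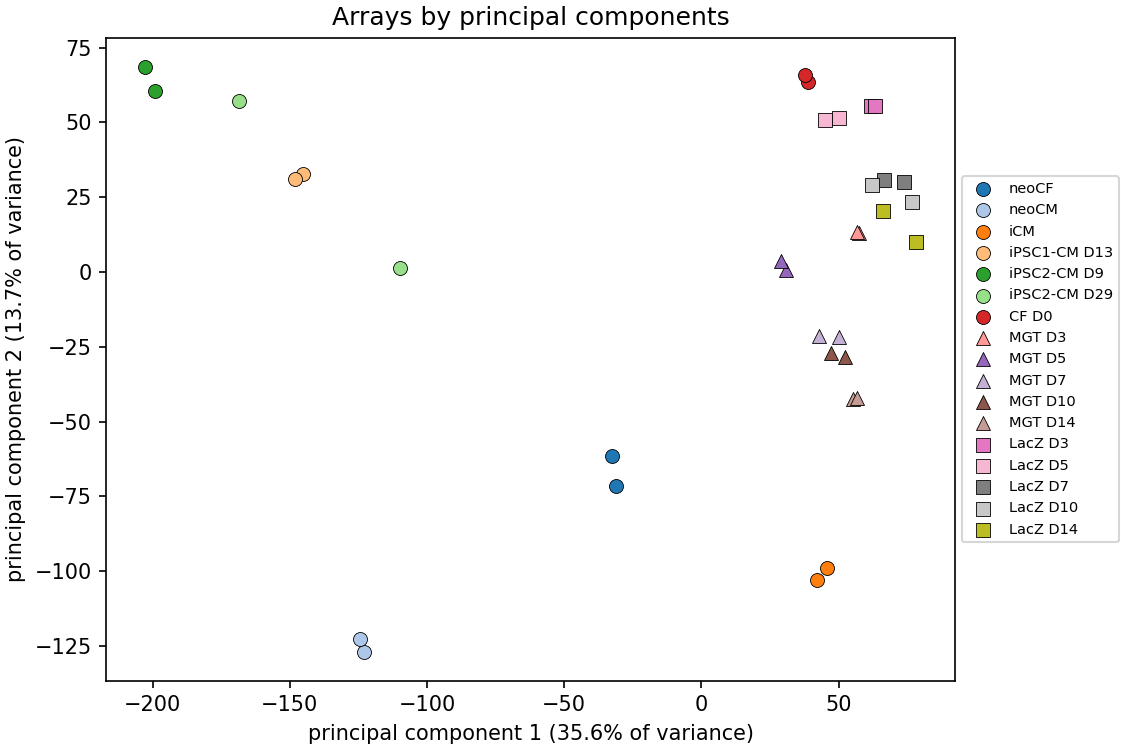
The 34 arrays on the first 2 principal components of the tested genes, each point 1 array, coloured by group.

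The reference for both routes is the difference between cardiomyocytes and fibroblasts of the newborn heart, which lay in contractile, oxidative and immune genes. All 22 (22 adjusted over the list alone) sarcomere genes rose in neoCM (median log2 change 4.92, camera adjusted p = 4.4e-15, then adjusted p = 0.047), led by the atrial light chain Myl7 (6.40 ± 0.46) and Csrp3, which anchors the Z-disc (5.91 ± 0.46). Every mitochondrial respiratory gene on its list was also higher, 26 of 26 (26 adjusted over the list alone, camera adjusted p = 8.6e-14, then adjusted p = 0.14), with the heart and muscle cytochrome oxidase subunits Cox7a1 (5.47 ± 0.31) and Cox8b (5.22 ± 0.21) at the top. Fatty acid oxidation followed with 22 of 26 (22 adjusted over the list alone) higher (camera adjusted p = 4.0e-13, then adjusted p = 0.08), including the muscle carnitine transferase Cpt1b (5.48 ± 0.32) and Ppargc1a, a coactivator of mitochondrial genes (5.10 ± 0.23). Of the isoforms typical of adult heart, 15 of 15 (15 adjusted over the list alone) were higher (camera adjusted p = 8.4e-12, then adjusted p = 1.4e-04), among them muscle creatine kinase Ckm (5.76 ± 0.42) and the titin cap Tcap (5.67 ± 0.32). Calcium handling and ion channels showed 19 of 21 (19 adjusted over the list alone) higher (camera adjusted p = 6.8e-10, then adjusted p = 5.5e-05), with the calcium pump regulator Sln at 6.57 ± 0.56 and the atrial potassium channel Kcnj3 at least 41.2-fold higher.

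Macrophage and endothelial transcripts also differed between the primary preparations. In neoCM 15 of 16 (15 adjusted over the list alone) macrophage genes were lower (camera adjusted p = 2.7e-07, then adjusted p = 0.12), including Adgre1 (-4.96 ± 0.36) and the mannose receptor Mrc1 (-4.89 ± 0.93), and so were 14 of 15 (14 adjusted over the list alone) endothelial genes (camera adjusted p = 1.5e-06, then adjusted p = 0.08). The chemokine Ccl21a of lymphatic vessels fell by 6.96 (adjusted p = 6.8e-11). Smooth muscle and pericyte genes were higher in neoCM at 7 of 11 (7 adjusted over the list alone, camera adjusted p = 3.0e-04, then adjusted p = 0.014). Nppa, the atrial peptide, rose by 5.87 (adjusted p = 6.8e-11). The cardiac factor Tbx5 rose by 4.30 (adjusted p = 2.5e-09) and Gata4 by 1.22 (adjusted p = 4.9e-06). In all, 6137 of 19413 genes were called, 3013 higher and 3124 lower (limma, adjusted p under 0.05 and at least 2-fold). Cell type coincides with scan day in this comparison, so the 2 cannot be told apart, and 6322 genes were called with slide as a random block. Here and below, that block cannot remove a slide difference, as the 2 sides share no slide. The fibroblast arrays themselves held cardiomyocyte transcripts, with Myh6 at 5.52 ± 0.34 (mean ± SD, log2 against the array's 75th percentile) beside 8.65 ± 0.07 in neoCM and 2.21 ± 0.04 in CF D0. Contrasts with neoCF start from that level. With CF D0 in place of neoCF, a reference chosen after seeing the data, endothelial genes (median -0.57, camera adjusted p = 0.62) and Mrc1 (-1.26, adjusted p = 0.25) were no longer called lower.

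Cells 4 weeks into direct reprogramming carried more of many contractile transcripts than neoCF and less of the proliferative and vascular ones. How far the direct route moved from fibroblasts shows in the sarcomere, where 15 of 22 (15 adjusted over the list alone) genes rose in iCM and 3 fell (3 adjusted over the list alone, camera adjusted p = 0.0073, then adjusted p = 0.67). Myl7 rose by 5.46 (adjusted p = 7.4e-09) and the M-band protein Myom2 by 4.83 (adjusted p = 1.1e-07), while the ventricular light chains moved the other way, Myl3 by -9.85 ± 0.54 and Myl2 by -8.26 ± 0.49. The ventricular list had median levels of 1.30 and 1.68 in neoCF and -4.21 and -3.30 in iCM. It was also low without the factors, at -3.51 and -3.50 in LacZ D14, beside -2.64 and -2.50 in MGT D14. The contrast with neoCF thus does not tie this fall to the factors. The endothelial list had 12 of 15 (12 adjusted over the list alone) lower (camera adjusted p = 6.6e-08, then adjusted p = 0.12), and the cell cycle list 24 of 29 (24 adjusted over the list alone) lower (camera adjusted p = 6.6e-08, then adjusted p = 0.6), with the proliferation antigen Mki67 at -4.56 ± 1.06 and the mitotic kinase Aurkb at least 23.4-fold lower. Imprinted growth genes were reduced as well, 10 of 13 (10 adjusted over the list alone, camera adjusted p = 1.8e-05, then adjusted p = 0.016), led by the fetal growth factor Igf2 (-8.40 ± 0.40) and Dlk1 (-5.20 ± 0.60). All 11 (11 adjusted over the list alone) early-response genes of tissue dissociation were lower (camera adjusted p = 3.3e-06, then adjusted p = 0.41), for example Fosb (-7.15 ± 0.81). These 3 lists were also low without the factors. In LacZ D14 the endothelial list lay at -1.5 and -1.8 (iCM -2.1 and -1.6). The imprinted list lay at 0.2 and -0.4 (iCM 1.7 and 1.7) and the dissociation list at -0.3 and 0.2 (iCM -0.1 and -0.1). The contrast does not tie their fall to the factors either. The cell cycle list lay at 2.0 and 2.0 in LacZ D14 (iCM -0.5 and -0.4). Fibroblast and matrix genes had no common direction, with 6 of 27 higher (6 adjusted over the list alone), such as Col8a1 (4.99 ± 0.61), and 5 lower (5 adjusted over the list alone), such as Postn (-3.43 ± 1.00).

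Among the largest single changes were the matrix protease Mmp3 (10.50 ± 1.63) and the senescence-associated inhibitor Cdkn2a (9.38 ± 0.69) upward. The neutrophil protein S100a9 (at least 3841-fold lower) and the globin Hbb-bt (at least 3641-fold lower) went downward. Mef2c lay lower than in neoCF (-1.16 ± 0.46, adjusted p = 0.039), a weak call. It ended after quantile normalization (-1.04, adjusted p = 0.075), with array weights (adjusted p = 0.2), with treat (adjusted p = 0.27) and on leaving out any 1 of the 4 arrays (adjusted p = 0.053 to 0.2). Against CF D0 Mef2c lay 2.40 higher. Limma called 7177 genes, 3275 higher and 3902 lower. The split turned with the scaling, to 3264 and 3161 after quantile normalization, 2677 and 2495 after normexp with quantile normalization, and 3100 and 2870 with the authors' values. Route and scan day cannot be told apart here, and 7384 genes were called with slide as a random block. With CF D0 in place of neoCF, 8773, 7867 and 7785 genes were called for neoCM, iCM and iPSC-CM, of which 3937, 3990 and 4000 were among the calls against neoCF. That change of reference ended the iCM calls of Mmp3 (1.79, adjusted p = 0.35), Col8a1 (0.98, adjusted p = 0.17) and the dissociation list (median -2.38, camera adjusted p = 0.17), and the imprinted list had a median of 0.01.

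Cardiomyocytes from pluripotent cells carried more glycolytic and contractile transcripts than neoCF and fewer of fibroblasts and immune cells. Glycolysis genes rose without exception, 19 of 19 (19 adjusted over the list alone, camera adjusted p = 8.8e-11, then adjusted p = 0.21), among them aldolase Aldoc (6.38 ± 0.45) and the glucose transporter Slc2a3 (5.16 ± 0.16). Sarcomere genes rose at 19 of 22 (19 adjusted over the list alone, camera adjusted p = 1.0e-06, then adjusted p = 0.32), with Myl7 at 5.79 ± 0.40 and the Z-disc actinin Actn2 at 4.68 ± 0.61. Fibroblast and matrix genes fell at 21 of 27 (21 adjusted over the list alone, camera adjusted p = 1.7e-06, then adjusted p = 0.48), with the collagen-binding Dcn at -9.07 ± 1.39. The 2 lines differed in this list, with median levels of 3.30 and 3.31 in iPSC1-CM and -0.72 and -0.39 in iPSC2-CM D9, against 4.48 and 4.71 in neoCF. Interferon-response genes were lower at 24 of 26 (24 adjusted over the list alone, camera adjusted p = 4.4e-13, then adjusted p = 0.19) and macrophage genes at 15 of 16 (15 adjusted over the list alone, camera adjusted p = 1.9e-10, then adjusted p = 0.19). Endothelial genes were lower at 14 of 15 (14 adjusted over the list alone, camera adjusted p = 4.0e-08, then adjusted p = 0.19), cytokine and complement genes at 15 of 16 (15 adjusted over the list alone, camera adjusted p = 4.9e-09, then adjusted p = 0.23) and dissociation genes at 11 of 11 (11 adjusted over the list alone, camera adjusted p = 6.3e-07, then adjusted p = 0.23). With CF D0 as the reference the endothelial list was no longer called (median -1.26, camera adjusted p = 0.055). Cfc1, a Nodal co-receptor, was at least 542-fold higher and the homeobox gene Alx1 was at least 112-fold higher.

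Of the 4 factors used to make the stem cells, Pou5f1 was still measurable on all 4 iPSC-CM arrays and at least 9.58-fold higher than in neoCF (adjusted p = 8.6e-04), a call that ended after normexp with quantile normalization (1.36, adjusted p = 0.12). Klf4 fell by 3.60 (adjusted p = 1.1e-13) and Myc fell by 2.25 (adjusted p = 1.5e-04), and Sox2 was not among the tested genes. Limma called 7216 genes, 3618 higher and 3598 lower. With other scalings lower calls were in excess, 2899 higher and 3909 lower after quantile normalization, 2235 and 3116 after normexp with quantile normalization, and 2581 and 3650 with the authors' values. The median gene moved by 0.21 in this contrast, and by 0.05 after quantile normalization. Both groups were scanned on the same day but on different slides, so slide and group cannot be told apart. With slide as a random block 7409 genes were called.

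The calls of the 2 routes against neoCF overlapped. Both raised 1027 genes and both lowered 1399, against 610 and 723 if the calls were independent, and 1037 genes went in opposite directions. The log2 changes correlated at r = 0.298 across genes. Part of this excess may come from the shared neoCF arrays. In 20 simulated draws of unchanged groups set against the same controls the correlation had a median of r = 0.578 and the covariance 0.097. The overlap there was 0 genes, but unchanged groups give few calls, so it does not size that part. The observed covariance was 0.919, which is 0.822 above the simulated one. The draws hold only the spread between arrays, not a trait of neoCF that shifts both contrasts alike.

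The central question of the series is how the products of the 2 routes differ. Set directly against each other, they differed in immune, matrix, metabolic and proliferative genes and in the ventricular light chains. Every interferon-response gene was higher in iCM, 26 of 26 (26 adjusted over the list alone, camera adjusted p = 2.6e-13, then adjusted p = 0.25), including the antiviral Ifit3, which was measurable on 2 of the 4 iPSC-CM arrays (7.70 ± 0.60). Macrophage genes were higher at 14 of 16 (14 adjusted over the list alone, camera adjusted p = 2.3e-06, then adjusted p = 0.34), with C1qc, a complement subunit of macrophages, at 10.75 ± 0.71 and measurable on 2 of the 4 iPSC-CM arrays. Cytokine and complement genes were higher at 14 of 16 (14 adjusted over the list alone, camera adjusted p = 5.8e-06, then adjusted p = 0.45), for instance complement factor Cfb at least 399-fold higher. The fibroblast and matrix list was also higher, 19 of 27 (20 adjusted over the list alone, camera adjusted p = 4.1e-05, then adjusted p = 0.52), led by Dcn (8.59 ± 1.39) and the surface marker Thy1 (8.22 ± 0.91). Its median level was 5.1 and 4.9 in iCM, 3.3 and 3.3 in iPSC1-CM, and -0.7 and -0.4 in iPSC2-CM D9, so the gap was larger for the second line. Without the factors, LacZ D14 had median interferon levels of 2.3 and 1.9 (iCM 1.7 and 1.7). Its macrophage list lay at 4.5 and 4.7 (iCM 2.9 and 2.9) and its fibroblast list at 5.2 and 5.4. Cytokine and complement genes lay at 1.9 and 1.5 (iCM 3.0 and 3.2). The labels give no sort of the cells, and the comparison does not tie these gaps to the factors.

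In the other direction iCM carried less of glycolysis and of the cell cycle. Lactate export and glucose uptake genes were reduced, Slc16a3 at -6.81 ± 0.21 and Slc2a3 at -4.01 ± 0.16, within 16 of 19 (16 adjusted over the list alone) lower (camera adjusted p = 4.2e-06, then adjusted p = 0.45). Among cell cycle genes 25 of 29 (25 adjusted over the list alone) were lower (camera adjusted p = 1.3e-05, then adjusted p = 0.48), with Aurkb at least 21.9-fold lower. Imprinted growth genes were lower at 10 of 13 (10 adjusted over the list alone, camera adjusted p = 0.0012, then adjusted p = 0.13), with Igf2 at -7.84 ± 0.34. Ventricular genes were lower at 6 of 7 (6 adjusted over the list alone, camera adjusted p = 0.0019, then adjusted p = 0.34), above all Myl3 (-12.53 ± 0.47) and Myl2 (-8.92 ± 0.42). The ventricular list had median levels of 3.23 and 3.13 in iPSC1-CM and 4.52 and 4.67 in iPSC2-CM D9, beside -4.21 and -3.30 in iCM. Sarcomere genes went both ways and the list was not called, with 11 of 22 (11 adjusted over the list alone) lower (camera adjusted p = 0.1, then adjusted p = 0.71) and 4 higher (4 adjusted over the list alone), Myom2 (6.93 ± 0.43) and Tcap (4.02 ± 0.28) among the latter. Median levels of that list were 3.64 and 3.54 in iCM, 4.10 and 4.06 in iPSC1-CM, and 5.81 and 6.04 in iPSC2-CM D9. Pou5f1 was at least 7.12-fold lower in iCM (adjusted p = 9.7e-04), and no longer called after normexp with quantile normalization (-1.21, adjusted p = 0.16).

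**Figure D2:**
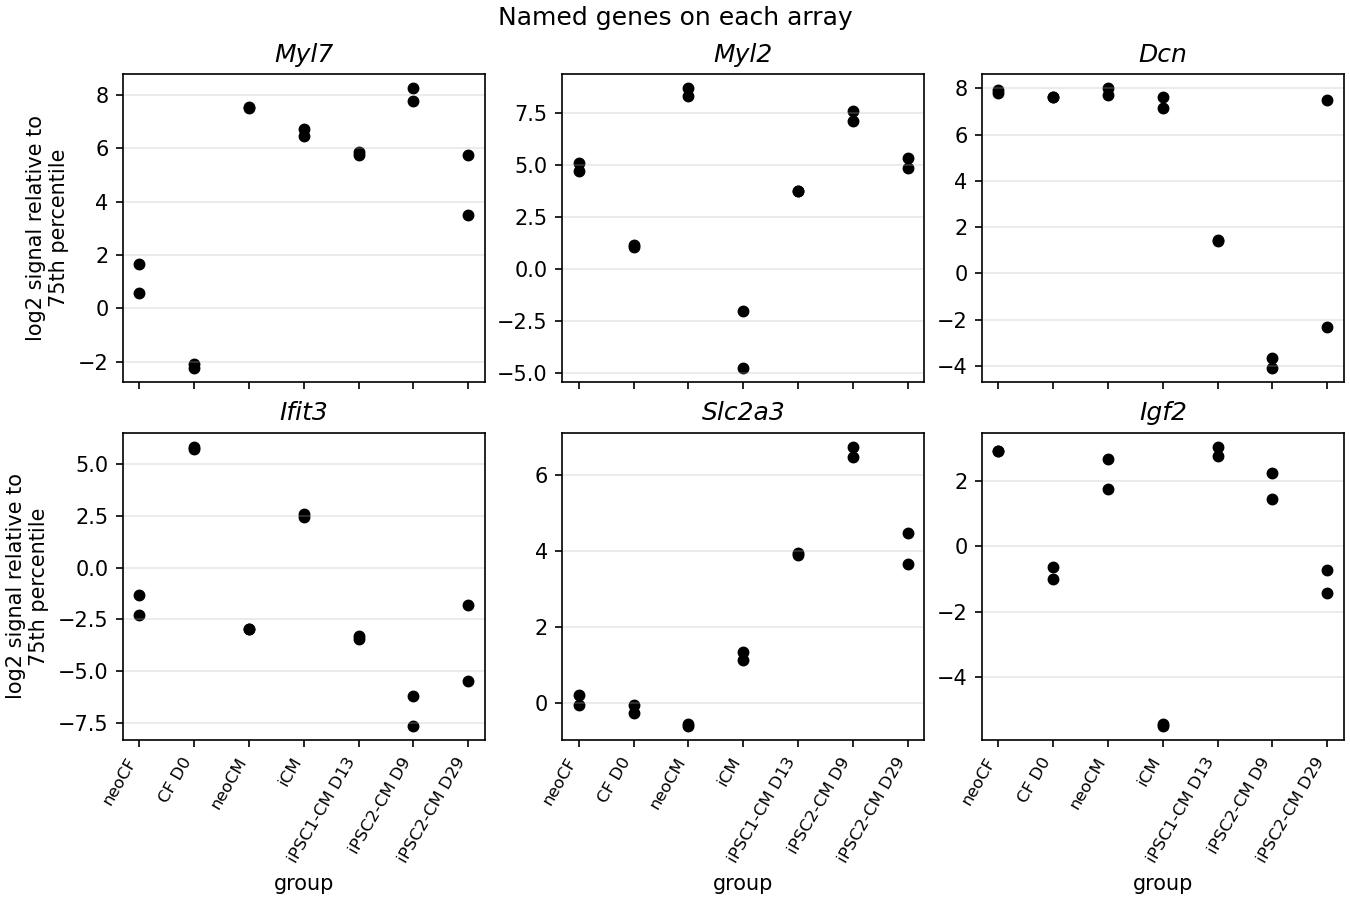
Levels of 6 named genes on every array of the end-point groups and CF D0, as log2 signal relative to the array's 75th percentile.

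Limma called 9093 of 19413 genes in this central comparison, 4000 higher in iCM and 5093 lower. That excess of lower calls depended on the scaling, as 4449 were higher and 3646 lower after quantile normalization, 3652 and 2772 after normexp with quantile normalization, and 4240 and 3170 with the authors' values. The median gene moved by -0.23 here and by -0.01 after quantile normalization. The list medians were several times larger, 5.01 for interferon and -1.80 for glycolysis. The arrays of the 2 routes were also scanned on different days, which cannot be separated from the route, and 9289 genes were called with slide as a random block. The iCM were also older in culture than the iPSC-CM, so age cannot be separated from the route either. At a similar age, described below, the direction of the cell cycle gap depended on the array.

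Beside cardiomyocytes from the newborn heart, iCM carried less of the adult isoforms and of the oxidative genes. All 15 (15 adjusted over the list alone) adult isoforms were lower (camera adjusted p = 5.2e-09, then adjusted p = 0.001), with Ckm at least 2040-fold lower and Myl2 at -11.87 ± 0.49. Respiratory genes were lower at 24 of 26 (24 adjusted over the list alone, camera adjusted p = 1.8e-08, then adjusted p = 0.27), for instance the heart subunit Cox6a2 (-5.53 ± 0.39), and fatty acid oxidation genes at 19 of 26 (19 adjusted over the list alone, camera adjusted p = 2.4e-06, then adjusted p = 0.24), for instance Cpt1b (-5.88 ± 0.32). Calcium handling and ion channels were reduced at 16 of 21 (16 adjusted over the list alone, camera adjusted p = 7.9e-06, then adjusted p = 0.001), with the connexin Gja5 at -9.70 ± 0.37 and the calcium pump inhibitor Pln at -6.97 ± 0.48. Of the sarcomere genes 15 of 22 (15 adjusted over the list alone) were lower (camera adjusted p = 1.9e-06, then adjusted p = 0.23). Interferon genes went up at 24 of 26 (24 adjusted over the list alone, camera adjusted p = 5.2e-09, then adjusted p = 0.17), including the antiviral synthetase Oas1a (6.52 ± 1.07). Markers of other cells and of dissociation differed too, with macrophage genes higher at 14 of 16 (14 adjusted over the list alone, camera adjusted p = 4.8e-05, then adjusted p = 0.24), dissociation genes lower at 10 of 11 (10 adjusted over the list alone, camera adjusted p = 4.8e-05, then adjusted p = 0.24) and red blood cell genes lower at 6 of 7 (6 adjusted over the list alone, camera adjusted p = 3.8e-05, then adjusted p = 0.0048). Smooth muscle genes had median levels of 1.0 and 1.2 in iCM against 4.6 and 4.8 in neoCM, and endothelial genes -2.1 and -1.6 against 0.7 and 0.5. Fibroblast and matrix genes were higher at 12 of 27 (12 adjusted over the list alone) and lower at 1 (1 adjusted over the list alone), and that list was not called (camera adjusted p = 0.14, then adjusted p = 0.76). The 3 reprogramming factors were below neoCM, with Mef2c at -2.24 ± 0.46, Gata4 at -2.03 ± 0.17 and Tbx5 at -4.05 ± 0.32.

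Limma called 7542 genes, 3492 higher in iCM and 4050 lower. Under other scalings more were higher than lower, 3672 and 3323 after quantile normalization, 2986 and 2743 after normexp with quantile normalization, and 3465 and 3128 with the authors' values. Here 1 neoCM array shares its slide with both iCM arrays. The other neoCM array lay alone on slide 1, so with slide as a fixed block the comparison rests on 1 neoCM array. That fit put the median of the adult isoforms at -2.99, beside -3.04 without a block. The median gene moved by -0.06, and by 0.05 after quantile normalization.

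Pluripotent-derived cardiomyocytes carried less of adult isoforms, calcium handling and fatty acid oxidation than neoCM. Adult isoforms were lower at 14 of 15 (14 adjusted over the list alone, camera adjusted p = 2.3e-08, then adjusted p = 0.0011), with the calcium store protein Casq2 at -8.08 ± 0.18. Calcium handling was lower at 15 of 21 (15 adjusted over the list alone, camera adjusted p = 2.1e-05, then adjusted p = 0.0011) and fatty acid oxidation at 19 of 26 (19 adjusted over the list alone, camera adjusted p = 1.2e-09, then adjusted p = 0.2), where the fatty acid transporter Cd36 (-4.25 ± 0.27) and the trifunctional enzyme subunit Hadha (-3.38 ± 0.26) led the fall. Among sarcomere genes 13 of 22 (13 adjusted over the list alone) were lower (camera adjusted p = 3.3e-04, then adjusted p = 0.45), chiefly Myom2 (-7.04 ± 0.43) and Tcap (-5.58 ± 0.28). Glycolysis genes were higher at 10 of 19 (10 adjusted over the list alone, camera adjusted p = 3.9e-04, then adjusted p = 0.45). Lower as well were dissociation genes at 9 of 11 (9 adjusted over the list alone, camera adjusted p = 5.4e-05, then adjusted p = 0.34), interferon genes at 18 of 26 (19 adjusted over the list alone, camera adjusted p = 4.3e-05, then adjusted p = 0.41) and macrophage genes at 11 of 16 (11 adjusted over the list alone, camera adjusted p = 3.9e-04, then adjusted p = 0.41). The same held for smooth muscle genes at 7 of 11 (7 adjusted over the list alone, camera adjusted p = 6.5e-04, then adjusted p = 0.028) and fibroblast and matrix genes at 18 of 27 (18 adjusted over the list alone, camera adjusted p = 0.0014, then adjusted p = 0.62). Hbb-b2, a globin of red blood cells, was at least 12310-fold lower. Limma called 7349 genes, 3785 higher and 3564 lower, with the median gene at 0.10 and at -0.01 after quantile normalization. That excess of higher calls turned into one of lower calls, 3315 higher and 3938 lower after quantile normalization, 2324 and 3070 after normexp with quantile normalization, and 2850 and 3723 with the authors' values. Group and scan day coincide here as well, and 7522 genes were called with slide as a random block.

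To compare the routes at a similar age, iCM of 4 weeks were set against iPSC2-CM D29. They stood above iPSC2-CM D29 in interferon genes at 26 of 26 (26 adjusted over the list alone, camera adjusted p = 1.9e-12, then adjusted p = 0.28), macrophage genes at 14 of 16 (14 adjusted over the list alone, camera adjusted p = 2.8e-08, then adjusted p = 0.28) and fibroblast genes at 24 of 27 (24 adjusted over the list alone, camera adjusted p = 2.8e-08, then adjusted p = 0.44). Smooth muscle myosin Myh11 was higher in iCM (4.18 ± 0.22), and the ventricular Myl3 (-11.75 ± 0.54) and Myl2 (-8.46 ± 0.49) were lower. Glycolysis genes were lower in iCM at 13 of 19 (13 adjusted over the list alone, camera adjusted p = 5.3e-05, then adjusted p = 0.44). Cell cycle genes were lower at 13 of 29 (13 adjusted over the list alone, camera adjusted p = 0.0145, then adjusted p = 0.78). The cell cycle list had median levels of -0.53 and -0.39 in iCM. It lay at 2.63 in iPSC2-CM D29 replicate 1 and at -1.3 in replicate 2, so its direction depended on the array. Pou5f1 was at least 63.3-fold lower in iCM (adjusted p = 1.4e-05). Limma called 8337 genes, 3435 higher and 4902 lower. The split was 4236 higher and 3096 lower after quantile normalization, 3383 and 2451 after normexp with quantile normalization, and 3988 and 2845 with the authors' values. The median gene moved by -0.23, and by 0.05 after quantile normalization. Scan day coincides with the route, and 8515 genes were called with slide as a random block. The 2 day-29 arrays stand far apart, with median levels of 3.05 and -0.89 for the fibroblast list and -3.30 and -4.65 for the macrophage list, so each value above averages over that gap. Array weights gave 2115 called genes, without Pou5f1 (adjusted p = 0.17). A fit of only these 4 arrays called 1573 genes, without Pou5f1 (-7.14, adjusted p = 0.098).

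From day 9 to day 29 fetal isoforms and smooth muscle genes fell in the second line, and genes of several other cell types moved. Fetal cardiomyocyte isoforms fell at 7 of 9 (7 adjusted over the list alone, camera adjusted p = 9.0e-06, then adjusted p = 0.039), with skeletal actin Acta1 at -4.70 ± 0.37 and the slow myosin Myh7 at -4.13 ± 0.61. Smooth muscle genes fell at 9 of 11 (9 adjusted over the list alone, camera adjusted p = 4.1e-05, then adjusted p = 0.013), with calponin Cnn1 at -5.43 ± 0.73. Imprinted growth genes were lower at 6 of 13 (6 adjusted over the list alone, camera adjusted p = 1.2e-04, then adjusted p = 0.024). Glycolysis genes were lower at 7 of 19 (7 adjusted over the list alone, camera adjusted p = 9.0e-06, then adjusted p = 0.27) and endothelial genes at 10 of 15 (11 adjusted over the list alone, camera adjusted p = 4.5e-05, then adjusted p = 0.14), while interferon genes were higher at 14 of 26 (14 adjusted over the list alone, camera adjusted p = 8.9e-05, then adjusted p = 0.37) and cytokine and complement genes at 10 of 16 (10 adjusted over the list alone, camera adjusted p = 1.2e-04, then adjusted p = 0.37). Endoderm and liver genes had median levels of 1.51 and -5.51 on the 2 day-29 arrays. Sarcomere genes fell at 15 of 22 (15 adjusted over the list alone, camera adjusted p = 1.7e-04, then adjusted p = 0.37), while 1 rose (1 adjusted over the list alone), Myom2 by 5.26 (adjusted p = 7.6e-08). Without iPSC2-CM D29 replicate 1 the calls ended for the sarcomere list (median -0.50, camera adjusted p = 0.056), the interferon list (median 0.59, camera adjusted p = 0.36) and the cytokine list (median 0.61, camera adjusted p = 0.36). Without replicate 2 the endothelial call ended (median -1.19, camera adjusted p = 0.11). Limma called 4709 genes, 2851 higher and 1858 lower, all on 1 slide. The 2 day-29 arrays differ far more than any other pair. Those p-values take their spread from all 17 groups and so understate it here. With only the 4 arrays of this comparison limma called 0 genes, though 2503 had unadjusted p under 0.05.

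The 2 iPSC lines differed in matrix, sarcomere and Y-linked genes. Cells of the first line at day 13 carried more matrix transcripts than cells of the second at day 9, 23 of 27 (23 adjusted over the list alone, camera adjusted p = 1.5e-10, then adjusted p = 0.52), including the proteoglycan Lum (10.12 ± 1.48). The Y-linked genes Ddx3y (at least 388-fold higher) and Eif2s3y (at least 386-fold higher) were measurable in the first line and not in the second. Sarcomere genes were lower at 12 of 22 (12 adjusted over the list alone, camera adjusted p = 7.1e-04, then adjusted p = 0.52) and fetal isoforms at 7 of 9 (8 adjusted over the list alone, camera adjusted p = 7.1e-04, then adjusted p = 0.36), with Myl2 at -3.59 ± 0.49 and the natriuretic peptide Nppb at -4.16 ± 0.60. Limma called 4150 genes on 1 slide, 2318 higher and 1832 lower. Line and day cannot be told apart, and the median gene moved by -0.11, or -0.01 after quantile normalization.

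Within the first 2 weeks sarcomere genes were higher with the 3 factors than with LacZ as a list on each day from 3 to 14. Of the delivered factors, Mef2c lay 6.78 ± 0.46 above LacZ on day 3 and 2.26 ± 0.46 on day 14, where the call ended with array weights (adjusted p = 0.074). Gata4 (0.22 ± 0.17 on day 3) and Tbx5 (0.39 ± 0.32) were called on no day. Whether these 3 probes read the part of each gene that the virus carries was not determined here, so the values do not test the delivery. Sarcomere genes were higher at 15 of 22 (15 adjusted over the list alone) on day 3 (camera adjusted p = 6.4e-27, then adjusted p = 0.012), 18 of 22 (19 adjusted over the list alone) on day 5 (camera adjusted p = 7.7e-34, then adjusted p = 0.0046), and 19 of 22 (19 adjusted over the list alone) on day 7 (camera adjusted p = 5.6e-39, then adjusted p = 0.0031). The counts were 18 of 22 (19 adjusted over the list alone) on day 10 (camera adjusted p = 1.7e-41, then adjusted p = 0.0023) and 18 of 22 (18 adjusted over the list alone) on day 14 (camera adjusted p = 1.2e-34, then adjusted p = 0.0055). Myl7 led the named genes already on day 3 (8.15 ± 0.46) and reached 10.26 ± 0.46 on day 10. Cardiac actin Actc1 stood at 9.69 ± 0.25 on day 5 and 10.76 ± 0.25 on day 14. The level of the alpha-myosin Myh6 in MGT cells was 2.31 on day 3, 3.11 on day 5, 6.31 on day 7 and 7.17 on day 10, when it lay 9.88 ± 0.28 above LacZ.

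**Figure D3:**
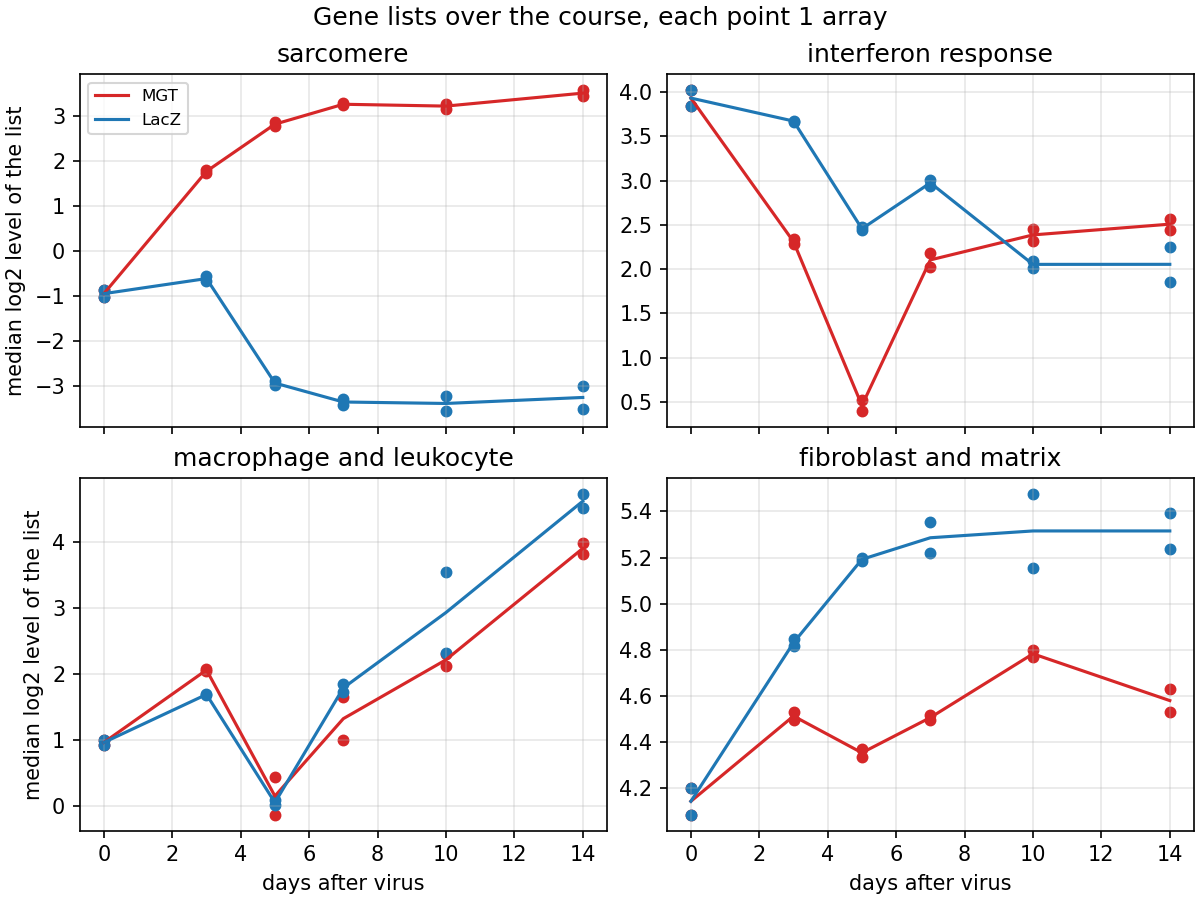
Median log2 level of 4 gene lists on each array of the course, days 0 to 14 after virus, for MGT and LacZ.

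Calcium handling genes and adult isoforms lay above LacZ over the same days. The calcium channel Ryr2 rose by 5.51 on day 3 (adjusted p = 2.0e-07), and Sln by 6.70 on day 3 and 11.68 on day 7 (adjusted p = 7.7e-08 and adjusted p = 9.7e-12). Calcium handling genes were higher at 9 of 21 (10 adjusted over the list alone) on day 3 (camera adjusted p = 4.7e-08, then adjusted p = 2.1e-04) and 13 of 21 (14 adjusted over the list alone) on day 14 (camera adjusted p = 2.1e-15, then adjusted p = 1.9e-06). Adult isoforms were higher at 5 of 15 (5 adjusted over the list alone, camera adjusted p = 2.7e-09, then adjusted p = 5.1e-04) and 9 of 15 (9 adjusted over the list alone, camera adjusted p = 1.0e-14, then adjusted p = 3.0e-05) on the same days. From day 3 to day 14 the median level of the calcium handling list went from -0.75 and -0.92 to -0.27 and -0.31 in MGT and from -2.72 and -2.76 to -3.35 and -3.62 in LacZ. That of the adult isoforms went from -0.39 and -0.53 to 0.94 and 0.94 in MGT and from -3.08 and -3.32 to -4.62 and -5.02 in LacZ, so part of the widening lies in the control. The oxygen-binding Mb stood at least 249-fold higher on day 10. The skeletal muscle list was called from day 5 on, with 2 of 11 (4 adjusted over the list alone) higher on day 5 (camera adjusted p = 0.0088, then adjusted p = 0.25), 4 of 11 (4 adjusted over the list alone) on day 7 (camera adjusted p = 0.0011, then adjusted p = 0.16) and 3 of 11 (3 adjusted over the list alone) on day 10 (camera adjusted p = 0.011, then adjusted p = 0.3). On day 14 it had 3 of 11 (4 adjusted over the list alone) higher (camera adjusted p = 0.0019, then adjusted p = 0.17), fast troponin Tnnt3 among them (7.36 ± 0.43), though the list was not called without LacZ D14 replicate 1 (median 0.35, camera adjusted p = 0.066).

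Some lists lay lower in MGT than in LacZ. Interferon genes were below LacZ on day 3 at 7 of 26 (8 adjusted over the list alone, camera adjusted p = 2.7e-09, then adjusted p = 0.26) and on day 5 at 16 of 26 (16 adjusted over the list alone, camera adjusted p = 5.3e-11, then adjusted p = 0.19), with the interferon regulator Irf7 at -2.55 ± 0.29. On day 7 the list still had lower median levels in MGT (2.18 and 2.03) than in LacZ (2.94 and 3.01). No interferon gene was called on days 10 and 14. Endothelial genes were lower at 1 of 15 (1 adjusted over the list alone) on day 3 (camera adjusted p = 0.019, then adjusted p = 0.73), 4 of 15 (7 adjusted over the list alone) on day 5 (camera adjusted p = 0.0087, then adjusted p = 0.49) and 8 of 15 (9 adjusted over the list alone) on day 7 (camera adjusted p = 7.7e-05, then adjusted p = 0.21). They were lower at 6 of 15 (8 adjusted over the list alone) on day 10 (camera adjusted p = 0.0027, then adjusted p = 0.37), and at 4 of 15 (5 adjusted over the list alone) on day 14, when the list was not called (camera adjusted p = 0.089, then adjusted p = 0.68), though it was after quantile normalization. Fibroblast and matrix genes gave 0 calls on day 3 and 6 of 27 (8 adjusted over the list alone) lower on day 14 (camera adjusted p = 0.003, then adjusted p = 0.78). Imprinted growth genes were lower on day 10 at 5 of 13 (5 adjusted over the list alone, camera adjusted p = 1.7e-04, then adjusted p = 0.0079), with Dlk1 at -5.20 ± 0.60. The centromere histone Cenpa was the only cell cycle gene called higher on day 14 (2.19 ± 0.27).

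Limma called 979 genes on day 3 (618 higher and 361 lower), 1601 on day 5 (954 and 647), 1696 on day 7 (1031 and 665), 1675 on day 10 (1018 and 657) and 2561 on day 14 (1133 and 1428). Both groups of a day shared 1 slide on days 3 to 10. On day 14 they lay on different slides, so slide and factors cannot be told apart, and 2846 genes were called with slide as a random block. The day 14 split also turned with the scaling, to 1324 higher and 761 lower after quantile normalization, 862 and 625 after normexp with quantile normalization, and 1129 and 772 with the authors' values. The median gene moved by -0.14 on day 10 and -0.13 on day 14, against -0.06 and -0.02 after quantile normalization.

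Averaged over the 5 days, the factors raised 1087 genes and lowered 961 (2048 called by limma, 10 arrays a side). Sarcomere genes were higher at 19 of 22 (19 adjusted over the list alone, camera adjusted p = 1.2e-28, then adjusted p = 0.0095), Myl7 by 9.65 (adjusted p = 5.5e-18) and the embryonic light chain Myl4 by 5.26 (adjusted p = 1.7e-20). The Wnt inhibitor Sfrp1 fell by 3.34 (adjusted p = 1.5e-08) and the matrix protein Smoc1 fell by 3.60 (adjusted p = 7.5e-13). Days 3 to 10 alone, where both groups share slides, gave 1922 called genes, 1794 of them also called over all 5 days. The split was 1144 higher and 782 lower after quantile normalization, 753 and 446 (1199 in all) after normexp with quantile normalization, and 933 and 605 with the authors' values.

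The effect of the factors differed between day 14 and day 3 in 872 genes, 428 with a larger log2 difference on day 14 and 444 with a smaller one. Sarcomere genes gained over LacZ at 15 of 22 (16 adjusted over the list alone, camera adjusted p = 3.6e-23, then adjusted p = 0.03), Myh6 by 10.30 (adjusted p = 3.7e-12), while the difference for Mef2c fell by 4.52 (adjusted p = 2.3e-04) and that for Dlk1 fell by 4.29 (adjusted p = 0.0043). Interferon genes gained over LacZ at 7 of 26 (7 adjusted over the list alone, camera adjusted p = 3.4e-11, then adjusted p = 0.18), among them the chemokine Cxcl10 (2.88 ± 0.44). Over these days the median level of the sarcomere list went from 1.80 and 1.74 to 3.57 and 3.45 in MGT, and from -0.56 and -0.67 to -2.99 and -3.51 in LacZ. That of the interferon list went from 2.34 and 2.28 to 2.45 and 2.57 in MGT, and from 3.67 and 3.68 to 2.25 and 1.85 in LacZ. The interferon gain over LacZ thus lies largely in the control, and the sarcomere gain in both. The split was 430 and 221 after quantile normalization, 418 and 251 after normexp with quantile normalization, and 476 and 279 with the authors' values. Leaving out 1 array gave 484 to 1632 called genes.

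Genes moved by the factors often went the way of the primary cardiomyocyte difference. On day 3, 442 genes were called in the same direction in MGT against LacZ and in neoCM against neoCF, 303 higher in both and 139 lower in both, where independent calls would give 95.9 and 58.1. Of the calls on that day this was 45.1%, and 138 genes went in opposite directions. The same counts were 727 on day 5, 802 on day 7 and 765 on day 10, or 45.4%, 47.3% and 45.7% of the calls. By day 14 it was 936 genes, 512 higher in both (176 if independent) and 424 lower in both (230 if independent), or 36.5% of the calls, with 400 in opposite directions. The correlation of log2 changes across genes was r = 0.203, 0.241, 0.307, 0.291 and 0.251 from day 3 to day 14. No array is in both comparisons.

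By day 14 the fibroblast cultures with LacZ virus had changed even without the factors. Macrophage genes rose from day 0 at 13 of 16 (15 adjusted over the list alone, camera adjusted p = 3.1e-04, then adjusted p = 0.55), C1qc by 5.72 (adjusted p = 1.0e-05) and the fractalkine receptor Cx3cr1 by 9.63 (adjusted p = 2.7e-13). Interferon genes fell at 17 of 26 (17 adjusted over the list alone, camera adjusted p = 5.0e-07, then adjusted p = 0.55). The neutrophil chemokine Cxcl5 fell by 9.32 (adjusted p = 9.0e-12). Sarcomere genes fell at 15 of 22 (15 adjusted over the list alone, camera adjusted p = 3.1e-04, then adjusted p = 0.58), with Myh6 at -5.49 ± 0.28 and Actc1 at -5.26 ± 0.25. The dissociation list went from median levels of 1.31 and 1.19 in CF D0 to -0.25 and 0.19 in LacZ D14. Limma called 5366 genes on 1 slide, 3052 higher and 2314 lower. LacZ D14 replicate 2 was the dimmest array, with a median replicate-spot variation of 5.91%. The median gene moved by 0.10, and by -0.01 after quantile normalization. Virus and time in culture cannot be told apart, as the series holds no uninfected culture of day 14.

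The 2 fibroblast references were themselves far apart. Day-0 cells of the course exceeded neoCF in interferon genes at 24 of 26 (25 adjusted over the list alone, camera adjusted p = 6.6e-10, then adjusted p = 0.18), Ifit3 by 7.60 (adjusted p = 2.0e-08) and Ifit1 by 7.26 (adjusted p = 3.7e-09). They carried less of the adult isoforms, 15 of 15 (15 adjusted over the list alone, camera adjusted p = 1.7e-09, then adjusted p = 8.6e-04), and of the sarcomere, 19 of 22 (19 adjusted over the list alone, camera adjusted p = 9.9e-07, then adjusted p = 0.26), with the giant spring protein Ttn at -4.17 ± 0.52. Imprinted growth genes were lower at 10 of 13 (10 adjusted over the list alone, camera adjusted p = 2.3e-06, then adjusted p = 0.0036), for instance Peg3 (-4.77 ± 0.33), and the protease inhibitor Timp1 was higher (5.02 ± 0.15). Endothelial genes were lower at 10 of 15 (10 adjusted over the list alone, camera adjusted p = 1.3e-04, then adjusted p = 0.2) and dissociation genes at 9 of 11 (10 adjusted over the list alone, camera adjusted p = 0.0011, then adjusted p = 0.4). Mef2c fell by 3.55 (adjusted p = 2.3e-06) and Tbx5 fell by 2.19 (adjusted p = 1.2e-05). Limma called 6688 genes on 1 slide, 3156 higher and 3532 lower.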

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

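The test of day 14 against day 3 and the random splits in this part were planned before the values were seen, while the count over unnamed probes was chosen afterwards.

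The effect of the factors was not the same on day 14 and day 3. A limma test of that difference itself called 872 genes, which is why they stand here. Myh6 gained 10.30 and Cxcl10 gained 2.88 on the log2 scale, while Mef2c fell by 4.52 and Dlk1 fell by 4.29. For Myh6 part of the gain lies in the control, whose level went from 2.16 on day 3 to -3.28 on day 14, as MGT went from 2.31 to 7.17. On day 14 the 2 groups lie on different slides. On days 3 and 10 each pair shared a slide, and on day 10 Myh6 already lay 9.88 ± 0.28 above LacZ, Dlk1 stood at -5.20 ± 0.60 (levels on day 3: 0.18 in MGT, 0.56 in LacZ) and Mef2c at 3.59 ± 0.46, beside 6.78 ± 0.46 for Mef2c on day 3. Cxcl10 went from 2.13 in MGT and 4.04 in LacZ on day 3 to 3.31 and 3.12 on day 10. The change in these 4 genes was thus present where slides did not differ. The same holds for the sarcomere list, whose median difference was 2.54 on day 3, 5.71 on day 10 and 5.74 on day 14. The other called genes were not checked in this way, so slide stays open for them. The count ranged from 484 to 1632 when 1 array was left out, the highest without LacZ D14 replicate 1.

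Random splits of the 20 course arrays asked whether any grouping would give as many calls as MGT against LacZ. The real split, with day in the model, called 2060 genes. Of 100 splits, the real one included, 1 reached that number, the highest other one called 1704, and the median of the others was 0. That highest other split kept 16 of the 20 arrays on their real side. As single arrays were split, the replicates of a group could fall on opposite sides. The effect of the factors then enters the spread and lowers the count. The labels do not say whether replicates were separate cultures. The splits therefore cannot decide whether a random grouping of whole groups would reach the real count.

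Probes that no comparison uses also carried a signal. Of 17747 kept probes without a matched gene, 1046 were called by limma in MGT against LacZ over all days, 554 higher and 492 lower. That is 5.89% of them, beside 10.5% of the tested genes. What they measure was not determined here, and no explanation was tested.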

How the results depend on the processing

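Direction was kept almost throughout: of 1359 values for named lists under alternatives 1345 stayed on their side of the threshold, and of 2343 for named genes 2322 did. Of the rest, 8 list values and 20 gene values lost the call, 5 list values gained it, and 2 turned, both with CF D0 in place of neoCF (chosen after seeing the data): in iCM the imprinted list had a median of 0.01 and Mef2c stood at 2.40. All these list values use the preset correlation. The estimated correlation, under which far fewer lists were called, is not among these alternatives and is counted below. Quantile normalization, the authors' values, the stricter filter, the mean of all probes, eBayes with trend and robust, and slide as a fixed block (run for 1 count) or random block (run for 9) left every count they were run for within 1.5 times. The random block was run where the 2 sides share no slide, so its counts do not test for a slide difference. The fixed block rests on 1 neoCM array. Leaving out an array leaves its group with 1, assumed to vary like the others; this gave 484 to 1632 calls for the effect of day 14 against day 3 and stayed within 1.5 times elsewhere.

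After normexp with quantile normalization, calls were 1487 for MGT against LacZ on day 14, 1199 for the mean of days and 616 shared with the primary difference on day 14. With no filter, day 14 had 4754 and the day difference 2245. In fits of only the arrays compared, iCM against iPSC2-CM D29 had 1573, iPSC2-CM D29 against D9 0 (limma, with 2503 at unadjusted p under 0.05), MGT against LacZ on day 3 1598, the day difference 1638, and the direction shared on day 3 682. Array weights (0.03 to 4.32) gave 2115, 503, 1798, 1728 and 698 for the same 5. Without both day-29 arrays in the fit (chosen after seeing the data), day 3 had 1505, the day difference 1875 and the direction shared on day 3 664. The 2 day-29 arrays differ most, which raises the shared spread. The cause of the other moves was not tested.

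Dropping the fold minimum, which admits smaller changes, gave 9960 for neoCM against neoCF, 11248 for iCM and 12209 for iPSC-CM against neoCF, 11497 for iCM and 12150 for iPSC-CM against neoCM, 8355 for iPSC2-CM D29 against D9, 7755 between the lines, 1622, 2714, 2816, 2909 and 4626 for the factors from day 3 to day 14, 8289 for their mean, 9271 for LacZ D14 against CF D0, and 10607 for CF D0 against neoCF. Shared directions then numbered 786, 1285, 1405, 1393 and 1912 over the days, and shared calls of the 2 routes 4924. With treat against 1.5-fold, a harder test, D29 against D9 had 3004, the factors 516, 929, 1013, 995 and 1351, the day difference 227, and the shared directions 229, 423, 476, 456 and 522. Over the 18 comparisons, 220 lists were called at the preset correlation and 68 with an estimated one.

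The replicate block, with the number as an additive term, moved no count by over 1.5 times: 6168 for neoCM against neoCF, 9109 for iCM against iPSC-CM, 2588 for day 14, 870 for the day difference and 220 for the lists. The numbers gave little sign of pairing. Same-numbered arrays of the course correlated in their deviations at -0.134 to 0.170 over 55 pairs, 4 of them over 0.1. Those of the primary and end-point set did so at -0.059 to 0.175 over 15 pairs, 2 of them over 0.1. Low correlations do not exclude a shared isolation or culture, and the labels do not say.

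Signal over background limits the dim end: 19413 genes were tested with the filter, 22804 with none and 17548 with the stricter one, and LacZ D14 replicate 2 had the fewest spots above background, 28715.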

Other observations

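Of the tests in this part, the slide and culture tests on macrophage genes were written before their values were seen, and the others afterwards.

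In the cultures given only LacZ, marker transcripts of several cell types changed with time. The median level of the macrophage list was 1.00 and 0.93 on the CF D0 arrays, 0.10 and 0.01 on day 5, and 4.51 and 4.72 on day 14. Interferon genes went from 4.02 and 3.85 on day 0 to 2.25 and 1.85 on day 14, and endothelial genes from 1.38 and 1.15 to -1.51 and -1.80. The cardiomyocyte gene Myh6 kept its level to day 3 and was lower by day 5, at 2.21 ± 0.04 on day 0, 2.16 ± 0.01 on day 3 and -1.89 ± 0.09 on day 5 (mean ± SD, n = 2).

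The primary cardiomyocytes carried transcripts of other tissues. Red blood cell genes had median levels of 3.43 and 3.42 in neoCM against -2.11 and -2.53 in neoCF, and the lung surfactant gene Sftpc was 8.54 ± 0.99 higher in neoCM and measurable on 1 of the 2 neoCF arrays. The cell cycle list set iCM apart from the early course, with medians of -0.53 and -0.39 against 1.56 and 1.56 in MGT D14. Chromatin and DNA methylation genes were at 0.42 and 0.34 in iCM and at 1.42 and 1.42 in neoCF.

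The 2 iPSC2-CM D29 arrays differed in genes of several cell types. In replicate 1, 9 of 11 endoderm and liver genes were at least 2-fold higher (median 7.16), as were 23 of 27 fibroblast and 25 of 29 cell cycle genes, while 18 of 22 sarcomere genes were at least 2-fold higher in replicate 2 (median -1.87). Replicate spots varied by 2.98% and 2.93% on the 2 arrays, within the 2.31% to 5.91% of all arrays, so spot noise was not unusual on either. The difference of 0.0573 percentage points lay below the median of 0.229 for the other 16 pairs. Equal noise on both arrays would give such a difference at any size. These measures cover noise within an array only. The scanner software marked replicate 1 for evaluation and replicate 2 as in range, and 10 of 11 dissociation genes were at least 2-fold higher in replicate 2 (median -2.57). Other lineages were higher in replicate 1 too, with median levels of 1.0 and -3.3 for neural genes and -0.1 and -4.0 for cartilage, bone and fat. Smooth muscle (-0.9 and 0.2) and skeletal muscle genes (-2.9 and -1.9) went the other way. The values go with cells of several lineages, endoderm-like ones among them, beside the cardiomyocytes in replicate 1. Handling before hybridization and a mislabelled sample were not excluded. The design gives both arrays the same label and so names no difference between them to test.

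Cardiomyocyte transcripts in neoCF were weighed against the slide. All 22 sarcomere genes were higher on the same neoCF array, by 0.098 to 1.084 (median 0.517), while the median gene differed by 0.009. On that array 12 of 15 adult isoforms (median 0.44) and 5 of 7 ventricular genes (median 0.35) were higher too, but only 13 of 21 calcium handling genes (median 0.10), and so were 14 of 16 macrophage genes (median 0.50). The sarcomere values are consistent with RNA from a varying share of cardiomyocytes in the preparation. A slide effect is not, as CF D0 on the same slide lay at a median of -2.80 relative to neoCF over these genes. Cardiomyocyte genes made by the fibroblasts themselves were not tested.

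Macrophage transcripts in iCM were weighed in the same way. LacZ D14, scanned on the same day as iPSC-CM, lay 7.93 above it in the median of the list, which argues against scan day as the whole cause. On day 14 the list was not higher with the factors, as MGT D14 lay at -0.56 relative to LacZ D14, which lay on another slide. The series holds no LacZ culture of 4 weeks, so this does not test the factors in iCM. The list had median levels of 2.862 and 2.871 in iCM and of 2.846 and 2.575 in neoCF. Macrophages kept from the fibroblast isolation remain possible: all 16 genes were well above background on both LacZ D14 arrays, but up to 14 of 16 were on an iPSC-CM array too, so this test left the question open.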
